A study of Mus musculus with 4 samples.

How the data were processed

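RNA was measured in 4 libraries of wild-type mouse male germ cells, 2 from cultures with the solvent DMSO and 2 from cultures with CBR-5884. Per the series' design text the cells were sorted from cultured fetal testes and each condition has 2 biological replicates. Per the labels' protocols, RNA was taken with an RNeasy micro kit, 100 ng of total RNA entered each library, and libraries were made with a TruSeq RNA kit. Whether the kit version keeps the strand of the RNA, and how the fetal testes were assigned to cultures, are not given in the sources used here.

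Per the submitters' processing notes, fastp, kallisto and the genome build mm10 were used; versions and settings are not given in the sources used here. The deposited table holds 469612 lines, 1 for each transcript and library, for 117403 transcripts of 36088 genes. Each gene's value is repeated for each of its transcripts, so 1 line per gene and library was kept. Per the file headers it gives 2 measures, scaled reads per base and TPM (transcript abundance relative to the library total), both treated here as signal values. The deposited scaled reads are gene-level signal values divided by a factor per library and scaled by length. The deposited TPM are gene-level signal values that summed to 966761 to 1002976 per library, so they had been rescaled after the conversion to TPM. The ratio of both measures was 1 constant per gene times 1 constant per library, within a relative spread of 0.00026. The steps between low scaled reads gave the relative depth of the libraries, but 34.8 to 36.0% of low values (up to 20.5 steps) were whole multiples of the step at a tolerance of 0.05, so whole reads could not be recovered. The numbers of reads behind each library, estimated from the total and the step, were 22500000 to 28200000. The 95% intervals of single genes given below come from the spread between libraries, not from counting error. The intervals of list medians under Other observations come from 10000 resamplings of a list's genes. They hold no spread between libraries and treat genes as independent.

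Before the data were examined, a quasi-likelihood count test had been chosen, with a test on log2(TPM + 1) as the choice for a table without counts. Because the values are not counts, edgeR and DESeq2 were not used. The comparison was made with limma 3.58.1 in R 4.3.3 (limma-trend), two-sided, on log2(TPM + 1), over the 14920 genes with a mean TPM of at least 1 over the 4 libraries. The other 21168 genes were left out. A fold change is therefore on the log2(TPM + 1) scale and understates the change of low genes. All 4 libraries entered the fit, with no covariate, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. With 2 against 2 libraries the smallest two-sided p of an exact permutation test is 0.33, so no such test was used for single genes.

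The library names in the table carry a condition and the number 2 or 4, while the labels number replicates 1 and 2. The condition of each library is certain, and which labelled replicate it is remains open. Libraries are called here by condition and table number. Genes were named by the table's own symbols. Positions and gene types come from GENCODE M21 on GRCm38, the assembly also called mm10, which held 35872 of the 36088 genes. All coordinates are 1-based.

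A total of 32 gene lists were fixed before the data were examined: serine and folate metabolism, methionine cycle, amino acid response, tRNA synthetases, nucleotide synthesis, antioxidant genes, cholesterol synthesis, glycolysis, mitochondrially encoded mRNAs, replication, p53 targets, DNA methylation, H3K9 methylation, Polycomb, the germ cell stages and pathways, markers of other testis cells, ribosomal proteins, chaperones, immediate early genes, and germline genes silenced in somatic cells. The 30 lists with at least 5 tested members were tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over lists. This test compares a list with the other genes. It was repeated with a correlation estimated from these libraries and with fry, which tests whether a list moves on balance. Both repeats rest on the 2 residual degrees of freedom of this comparison, so they have little power over 30 lists.

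The rule for genes named in the text was also fixed beforehand. It takes a panel of 26 genes of serine metabolism and germ cell biology, whatever their result. Because fewer than 10 genes passed the threshold, it also takes the 10 genes with the smallest p among those with groups that do not overlap and a mean TPM of at least 5 (set as 5 CPM before the unit was known), skipping predicted genes, Rik clones and pseudogene names. Members of called lists are named as examples of their list. The fit was tested on 20 simulated tables of 14920 genes built on this comparison, each with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 44.5% of the 2-fold and 80.4% of the 4-fold changes, with 7.3 false calls per table on average. A list of 20 genes shifted by 0.30 on the log2 scale was called in 20 of 20 tables. The noise was drawn independently for each gene, so the simulation does not test camera on lists whose genes vary together. Estimated correlations in the real lists were 0.387 for cholesterol synthesis, 0.69 for ribosomal proteins and −0.034 for mitochondrially encoded mRNAs. The recovery holds only for tables with that many changed genes.

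For each named gene and each mitochondrially encoded mRNA except H2ac24, whose symbol differs in the reference, the share of 31-base words also present in transcripts of other genes of the table was counted in GENCODE M21 sequences, on either strand. Alternatives covered the filter on low values, the pseudocount, the measure, the scaling, protein-coding genes alone, robust variance estimates, stricter thresholds, the library number as a block, each library left out in turn, and the list test. Figures were drawn with matplotlib 3.10.9.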

Results

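RNA sequencing was carried out on male germ cells of wild-type mice, isolated by sorting from fetal testes kept in culture, to ask what part serine metabolism plays in the differentiation of these cells. Cultures received CBR-5884, described in the labels as an inhibitor of serine metabolism and known as an inhibitor of Phgdh, the first enzyme of serine synthesis from glucose, or its solvent DMSO. The sample titles give day 14. There were 2 libraries per condition, named biological replicates in the design text. The estimated depth was 24600000 reads for DMSO library 2, 22500000 for DMSO library 4, 28200000 for CBR-5884 library 2 and 25300000 for CBR-5884 library 4. Between 22100 and 22988 genes per library had a TPM above 0, and the 10 most abundant genes took 4.26 to 4.89% of the TPM. Correlations of log2(TPM + 1) across the tested genes, which are not independent replicates, lay between 0.977 and 0.986 for the 6 pairs of libraries. The highest was between DMSO library 2 and CBR-5884 library 2, and the value within the DMSO group was 0.978.

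The germ cell transcriptome was close between CBR-5884 and DMSO, and no gene passed the threshold. The 13 mRNAs encoded by the mitochondrial genome and the genes of cholesterol synthesis lay higher as lists with CBR-5884, and the heat shock and unfolded protein response list lay lower, led by Hspa1a and Hspa1b. These calls rest on camera with a preset correlation. With an estimated correlation the camera adjusted p was 0.463, 0.591 and 0.591, and 0 of 30 lists were called by that test or by fry. Both have little power with 2 residual degrees of freedom, so they cannot decide whether the lists moved. With the preset correlation, camera also called cholesterol synthesis (adjusted p = 0.00328) and the heat shock list (adjusted p = 0.029) between the libraries numbered 2 and 4. It did not call the mitochondrial list between those numbers (camera adjusted p = 0.499). Genes of serine synthesis, and most markers of germ cell stages, differed little. Of 14920 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.0965. At an unadjusted p under 0.05 there were 546 genes, 3.7% of those tested where chance gives 5%, of which 225 were higher and 321 lower with CBR-5884. The groups did not overlap for 4673 genes (31.3%), against 33.3% by chance for 2 against 2 libraries. The median half-width of the 95% interval was 0.37 on the log2 scale, or 1.3-fold, and 0.28, or 1.21-fold, for the 9538 genes with a mean TPM of 10 or more. Among alternatives chosen after the data were seen, robust variance estimates and the restriction to protein-coding genes each called 1 gene higher, and that restriction and the use of scaled reads each called Hspa1b lower.

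The genes with the smallest p among named genes with groups that did not overlap included the paired heat shock genes Hspa1b and Hspa1a, 4 mitochondrially encoded mRNAs, Phactr4, Prodh2, Lars2 and H2ac24. Hspa1b, an inducible cytosolic chaperone of the Hsp70 family on chromosome 17 from 34956436 to 34959238, had 152 ± 18.3 TPM with DMSO and 48.5 ± 7.45 TPM with CBR-5884 (SD, n = 2), a log2 fold change of −1.63 (SE 0.14; limma adjusted p = 0.141). Hspa1a, its near-identical neighbour from 34969190 to 34972156, had 73.3 ± 15.5 and 20.1 ± 4.98 TPM (SD, n = 2; log2 fold change −1.82, limma adjusted p = 0.253). Because 67.7% of the 31-base words of Hspa1b also occur in Hspa1a, the split of reads between both genes is uncertain. Their summed TPM was 201.8 and 249.5 in the DMSO libraries and 77.4 and 59.8 in the CBR-5884 libraries. Phactr4, which encodes an actin and protein phosphatase 1 binding protein (chromosome 4, 132355923 to 132422489), had 86.6 ± 4.65 TPM with DMSO and 58.6 ± 0.28 TPM with CBR-5884 (SD, n = 2; limma adjusted p = 0.570). Prodh2, a hydroxyproline dehydrogenase of mitochondria (chromosome 7, 30493622 to 30513402), had 16.5 ± 0.13 and 8.33 ± 0.62 TPM (SD, n = 2; limma adjusted p = 0.725). Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462666), had 676 ± 41.7 and 427 ± 65.3 TPM (SD, n = 2; limma adjusted p = 0.725). H2ac24, a histone H2A gene (chromosome 13, 21833026 to 21833507), had 66.8 ± 28.2 and 174 ± 15.6 TPM (SD, n = 2; limma adjusted p = 0.725); it belongs to a family of near-identical genes, so its share of reads is uncertain. Across all genes with a mean TPM of 10 or more, 23 had an absolute log2 fold change of at least 1, and 19 of these were pseudogenes or predicted genes.

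Enzymes of serine synthesis and of the folate pathway that serine feeds were abundant and close between the conditions. Phgdh, the known target of CBR-5884, had 251 ± 13.3 TPM with DMSO and 264 ± 1.53 TPM with CBR-5884 (SD, n = 2), a log2 fold change of 0.07 with a 95% interval from −0.11 to 0.26. Of its 31-base words, 55.5% also occur in other genes of the table, mostly pseudogenes such as Gm7901. Psat1, the next enzyme of the pathway, had 124 ± 3.99 and 136 ± 18.0 TPM (SD, n = 2), with an interval of −0.14 to 0.39. Psph, which completes serine, had 48.2 ± 2.04 and 49.5 ± 1.01 TPM (SD, n = 2), with an interval of −0.19 to 0.26. Shmt2, which turns serine into glycine in mitochondria, had 194 ± 8.91 and 219 ± 13.7 TPM (SD, n = 2; interval −0.02 to 0.38). Mthfd2, the next mitochondrial folate enzyme, had 140 ± 11.6 and 134 ± 6.59 TPM (SD, n = 2; interval −0.28 to 0.16). Of the 19 tested members of the serine and folate list, 0 passed the threshold over all genes, 0 did when adjusted over the list alone and 0 had an unadjusted p under 0.05 (limma). In this list 13 had a positive and 6 a negative fold change, and the list's camera adjusted p was 0.236 (median log2 fold change 0.07). Its median was 0.00 without DMSO library 2 and 0.02 without CBR-5884 library 4. The methionine cycle and transsulfuration list, which takes up folate-bound carbon and serine, had a median of 0.01 over 14 tested genes (camera adjusted p = 0.928). It was −0.06 without DMSO library 4 and 0.04 without CBR-5884 library 4.

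**Figure D1:**
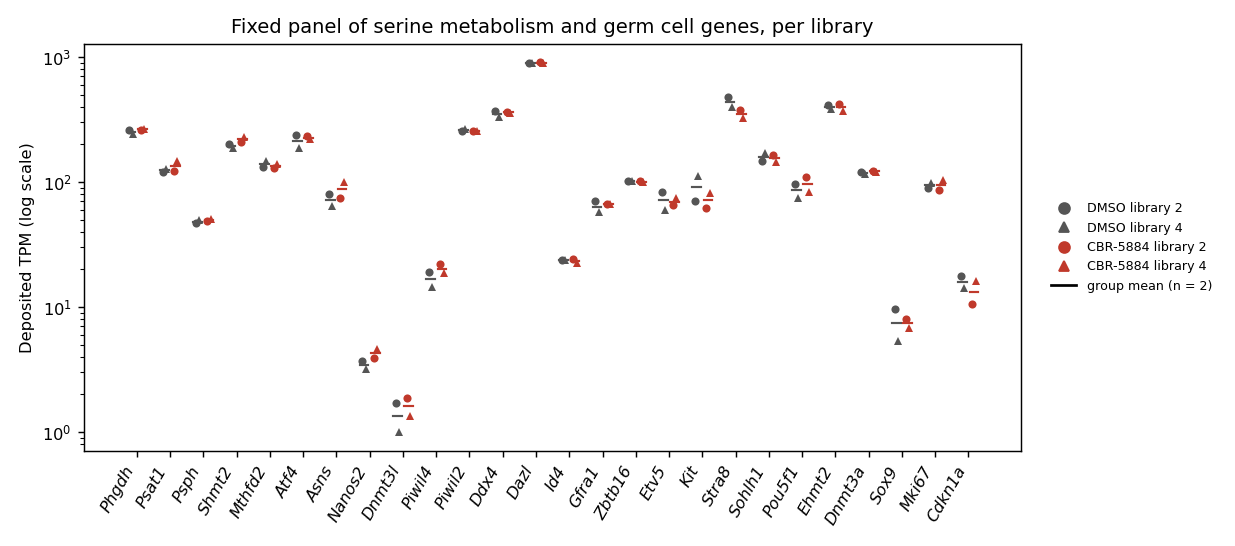
Deposited TPM (log scale) of the 26 panel genes in each of the 4 libraries, with grey points for DMSO, red points for CBR-5884, circles for library 2, triangles for library 4 and a line for the mean of each group (n = 2). Stra8 lies at 475.8 and 398.7 TPM in the DMSO libraries and at 375.7 and 322.8 TPM in the CBR-5884 libraries, while Dazl lies between 892 and 906 TPM in all 4.

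The amino acid response list, genes that the transcription factor Atf4 switches on when amino acids run short, lay higher with CBR-5884 by a small amount. Of its 27 tested members 21 had a positive fold change, with a median of 0.07 (camera adjusted p = 0.00548; adjusted p = 0.591 with an estimated correlation). With limma 0 of the 27 passed the threshold over all genes, 0 did when adjusted over the list alone and 0 had an unadjusted p under 0.05. Chac1, a glutathione-degrading enzyme, had 10.7 and 8.05 TPM in the DMSO libraries and 12.4 and 13.9 TPM in the CBR-5884 libraries. Slc1a5, a transporter of neutral amino acids including serine, had 18.4 and 19.3 TPM against 21.3 and 33.5 TPM. Asns, the asparagine synthetase, had 72.4 ± 11.8 and 87.5 ± 18.2 TPM, and Atf4 itself had 212 ± 34.8 and 226 ± 9.29 TPM (SD, n = 2). The call was lost without DMSO library 4 (median 0.03, camera adjusted p = 0.551) and without CBR-5884 library 4 (median 0.14, camera adjusted p = 0.061). Without DMSO library 2 the median was 0.19. Cytosolic aminoacyl-tRNA synthetases, many of them further targets of Atf4, had a median of −0.02 over 20 genes (camera adjusted p = 0.768), and of 0.01 without CBR-5884 library 2.

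Genes of cholesterol synthesis and uptake lay higher with CBR-5884 as a list. Of 22 tested members 19 had a positive fold change, with a median of 0.14 and a range of −0.06 to 0.34 (camera adjusted p = 3.23e-07). The adjusted p was 0.591 with an estimated correlation, which ended the call. With limma 0 of the 22 passed the threshold over all genes, 0 did when adjusted over the list alone, and 5 had an unadjusted p under 0.05. Lss, the lanosterol synthase, had 121 and 115 TPM in the DMSO libraries and 139 and 142 TPM in the CBR-5884 libraries. Idi1, which isomerises isopentenyl diphosphate, had 138 and 121 TPM against 163 and 148 TPM, and Insig1, a brake on the pathway that is itself induced by its regulator Srebf2, had 227 and 213 TPM against 252 and 261 TPM. The call held in each of the 4 fits that left out a library, though its median was 0.25 without DMSO library 2 and 0.07 without DMSO library 4.

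Mitochondrially encoded mRNAs, subunits of the respiratory chain and ATP synthase, lay higher with CBR-5884 as a list. Of the 13, 12 had a positive fold change, and the median was 0.51 (camera adjusted p = 1.75e-12; adjusted p = 0.463 with an estimated correlation, which ended the call). Over all genes 0 passed the threshold with limma, 10 had an unadjusted p under 0.05, and when adjusted over the list alone 9 were higher and 1 lower. mt-Nd4, a complex I subunit at positions 10167 to 11544 of the mitochondrial genome, had 1219 ± 74.0 TPM with DMSO and 1863 ± 41.7 TPM with CBR-5884 (SD, n = 2; log2 fold change 0.61, SE 0.09). mt-Nd5 (11742 to 13565) had 431 and 352 TPM in the DMSO libraries and 604 and 583 TPM in the CBR-5884 libraries, and mt-Nd6 (13552 to 14070), encoded on the other strand, had 349 ± 37.9 and 526 ± 46.0 TPM (SD, n = 2). mt-Nd5 and mt-Nd6 overlap at their ends, and strand use in counting is not given in the sources used here. mt-Nd3 (9459 to 9806) went the other way, with 338 ± 4.56 and 186 ± 20.2 TPM (SD, n = 2; log2 fold change −0.86, SE 0.09), the member lower when adjusted over the list alone. Its value is uncertain, because 98.1% of its 31-base words occur in the nuclear pseudogene Gm28438. The sum of mt-Nd3 and Gm28438 was 1739 and 2204 TPM in the DMSO libraries and 1978 and 2317 TPM in the CBR-5884 libraries. The value of mt-Nd4 is uncertain too, since 62.8% of its words occur in the nuclear copy Gm28439. Among the 6 members with under 20% of such shared words the median was 0.50. The 13 mRNAs took 2.96 and 3.17% of the TPM in the DMSO libraries and 3.71 and 4.19% in the CBR-5884 libraries.

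**Figure D2:**
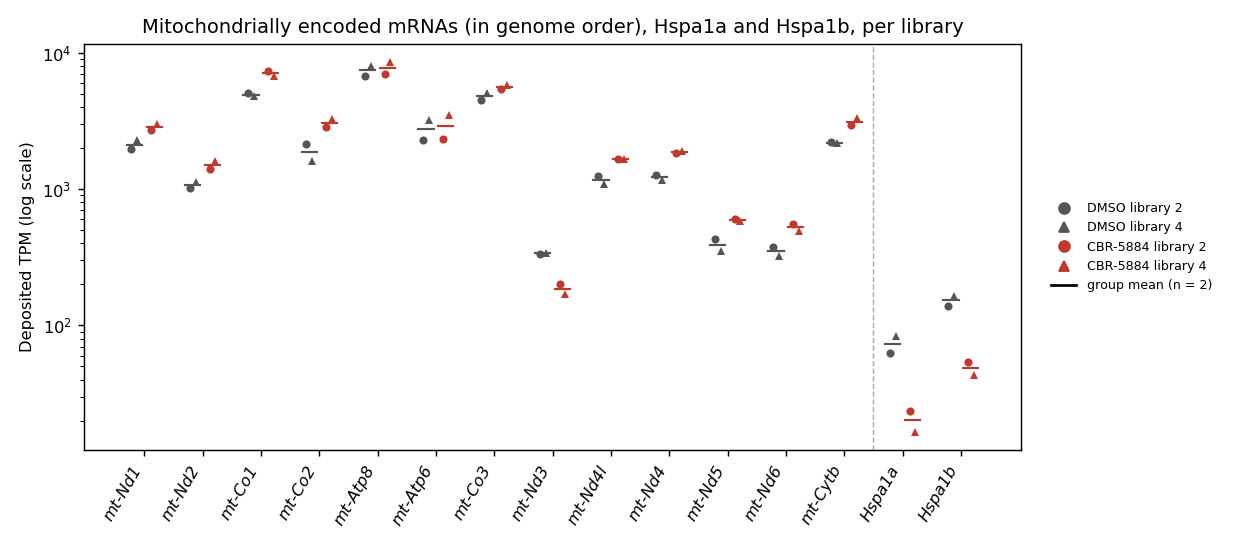
Deposited TPM (log scale) of the 13 mitochondrially encoded mRNAs in genome order and of Hspa1a and Hspa1b, in each of the 4 libraries, with grey points for DMSO, red points for CBR-5884, circles for library 2, triangles for library 4 and a line for each group's mean (n = 2). mt-Nd4 lies at 1271 and 1167 TPM with DMSO and at 1833 and 1892 TPM with CBR-5884, and Hspa1b at 139 and 165 TPM against 53.8 and 43.3 TPM.

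The heat shock and unfolded protein response list lay lower with CBR-5884, with 20 of 24 tested members at a negative fold change and a median of −0.09 (camera adjusted p = 0.000138; adjusted p = 0.591 with an estimated correlation). Over all genes 0 passed the threshold with limma, and 3 had an unadjusted p under 0.05. Adjusted over the list alone 2 were lower, Hspa1a and Hspa1b, both cytosolic chaperones. Without these 2 the other 22 had a median of −0.08 (camera adjusted p = 0.0166). That part is not among the lists fixed beforehand and was tested only with the preset correlation. Dnajb1, a co-chaperone of Hsp70, had 72.7 and 85.9 TPM in the DMSO libraries and 65.2 and 69.5 TPM in the CBR-5884 libraries, and Manf, a secreted protein of the endoplasmic reticulum stress response, had 229 and 227 TPM against 205 and 198 TPM. The call of the whole list was lost without DMSO library 4 (median −0.07, camera adjusted p = 0.16), and its median was −0.15 without DMSO library 2 and −0.05 without CBR-5884 library 2.

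Germ cell genes were abundant in all 4 libraries and differed little between the conditions. Dazl, an RNA-binding protein of germ cells, had 894 ± 3.40 TPM with DMSO and 901 ± 6.13 TPM with CBR-5884, and Ddx4, the germ cell RNA helicase, had 350 ± 26.6 and 362 ± 4.28 TPM (SD, n = 2). Genes of the spermatogonial stem cell state had similar levels. Id4 had 23.7 ± 0.20 and 23.4 ± 1.18 TPM, Gfra1, the receptor for the niche factor Gdnf, had means of 63.5 and 66.4 TPM, Zbtb16 had 102 ± 0.58 and 101 ± 0.70 TPM, and Etv5 had 71.7 ± 17.2 and 69.7 ± 6.86 TPM (SD, n = 2). Stra8, which retinoic acid induces at the start of differentiation and meiosis, had 437 ± 54.5 TPM with DMSO and 349 ± 37.4 TPM with CBR-5884 (SD, n = 2; log2 fold change −0.32, 95% interval −0.61 to −0.03), and was the 1 panel gene of 26 at an unadjusted p under 0.05 (limma adjusted p = 0.998). Kit, the receptor of differentiating spermatogonia, had 90.6 ± 29.1 and 72.3 ± 14.3 TPM, and Sohlh1, a transcription factor of the same step, had 160 ± 17.1 and 154 ± 12.7 TPM (SD, n = 2). Of the prospermatogonia genes in the panel, Nanos2 was at 3.45 ± 0.36 and 4.27 ± 0.48 TPM, Dnmt3l at 1.34 ± 0.49 and 1.60 ± 0.37 TPM and Piwil4 at 16.7 ± 3.16 and 20.3 ± 2.28 TPM, while Piwil2 had 260 ± 4.74 and 256 ± 0.98 TPM (SD, n = 2). The median level over the 17 tested prospermatogonia genes was 44.3 TPM with DMSO and 47.7 TPM with CBR-5884. Pou5f1 had 85.6 ± 16.4 and 96.7 ± 19.6 TPM (SD, n = 2).

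In the germ cell lists 0 genes passed the threshold with limma over all genes and 0 did when adjusted over the list alone; at an unadjusted p under 0.05 there were 3 in the meiotic list and at most 1 in each other list. Differentiating spermatogonia genes had 14 of 18 members at a negative fold change (median −0.08, camera adjusted p = 0.0606). That list was called without DMSO library 2 (median −0.14, camera adjusted p = 0.0158) and with no filter on low values (0.0475), while its median without DMSO library 4 was −0.03 (camera adjusted p = 0.802). With all libraries the adjusted p was 0.591 with an estimated correlation and 0.788 with fry. Spermatogonial stem and progenitor genes had 16 of 34 at a negative fold change (median 0.04, camera adjusted p = 0.287). Their median was −0.01 without CBR-5884 library 2 and 0.02 without DMSO library 4. Prospermatogonia genes had a median of 0.07 over 17 genes (camera adjusted p = 0.115). Fetal germ cell and pluripotency genes had a median of 0.10 over 16 (camera adjusted p = 0.387), or −0.02 without DMSO library 2 and 0.03 without DMSO library 4. General germ cell genes had a median of 0.05 over 16 (camera adjusted p = 0.0606) and piRNA pathway genes 0.05 over 24 (camera adjusted p = 0.111). Meiotic prophase genes had a median of 0.04 over 34 genes (camera adjusted p = 0.141), with Sycp3 at 189 and 162 TPM in the DMSO libraries and 196 and 192 TPM in the CBR-5884 libraries. Of 19 postmeiotic spermatid genes 12 had a mean under 1 TPM, and the 7 tested had a median of −0.03 (camera adjusted p = 0.867), or −0.10 without DMSO library 4 and 0.02 without CBR-5884 library 4.

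Calls among the germ cell lists changed with the library left out. Without DMSO library 2 the prospermatogonia (median 0.20, camera adjusted p = 0.0295), general germ cell (0.10, adjusted p = 0.0141) and piRNA lists (0.07, adjusted p = 0.0191) were called higher. Without DMSO library 4 their medians were 0.01 (camera adjusted p = 0.917), 0.00 (adjusted p = 0.917) and −0.01 (adjusted p = 0.924). The general germ cell list was also called without CBR-5884 library 4 (median 0.07, camera adjusted p = 0.0364) and with equal library totals (0.07, adjusted p = 0.0199). The meiotic list was called without CBR-5884 library 2 (0.11, adjusted p = 0.0427), while without CBR-5884 library 4 its median was −0.00 (camera adjusted p = 0.861). With all libraries and an estimated correlation the adjusted p was 0.662 for the general germ cell list and 0.591 for the prospermatogonia, piRNA and meiotic lists.

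Germline genes that DNA methylation keeps silent in somatic cells lay higher by a small amount, with 20 of 22 at a positive fold change and a median of 0.05 (camera adjusted p = 0.00637; adjusted p = 0.591 with an estimated correlation). With limma 0 of the 22 passed the threshold over all genes, 0 did when adjusted over the list alone and 1 had an unadjusted p under 0.05. The call was lost without DMSO library 4 (median 0.00, camera adjusted p = 0.82) and without CBR-5884 library 2 (median 0.04, camera adjusted p = 0.0721). Its median was 0.13 without DMSO library 2 and 0.09 without CBR-5884 library 4. Of its 22 genes 19 also stand in other lists. Brdt, a bromodomain protein of spermatocytes, had 36.5 and 35.6 TPM with DMSO and 43.0 and 42.8 TPM with CBR-5884.

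Enzymes that write or remove DNA and histone methylation, marks that draw on methyl groups from the folate and methionine cycles, did not pass the threshold in any list, over all genes or adjusted over the list alone (limma; 3 had an unadjusted p under 0.05). The 9 tested DNA methylation and demethylation enzymes had a median of −0.15 (camera adjusted p = 0.172). It was −0.05 without DMSO library 4 and −0.08 without CBR-5884 library 2. Dnmt1, the maintenance methyltransferase, had 384 and 378 TPM in the DMSO libraries and 323 and 347 TPM in the CBR-5884 libraries, and Dnmt3a had 118 ± 2.46 and 122 ± 2.07 TPM (SD, n = 2). H3K9 methylation genes had a median of −0.08 over 20 (camera adjusted p = 0.141), or −0.04 without CBR-5884 library 4, and Ehmt2, the H3K9 dimethylase, had 400.4 ± 20.6 and 397 ± 36.5 TPM (SD, n = 2). Polycomb and H3K27 methylation genes had a median of −0.00 over 19 (camera adjusted p = 0.507), with a mean of 0.03 and medians of −0.02 to 0.02 with a library left out.

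Genes of growth and division were also close. Ribosomal proteins lay slightly lower as a list, with 33 of 40 at a negative fold change and a median of −0.07 (camera adjusted p = 0.0193; adjusted p = 0.779 with an estimated correlation). That call was lost and the direction of the test turned without DMSO library 4 (median −0.02, camera adjusted p = 0.917) and without CBR-5884 library 4 (median 0.01, camera adjusted p = 0.414). The median was −0.11 without DMSO library 2 and −0.15 without CBR-5884 library 2. Rplp0 had 1628 and 1755 TPM in the DMSO libraries and 1577 and 1473 TPM in the CBR-5884 libraries. Purine and pyrimidine synthesis genes, whose products need folate-bound carbon, had 15 of 18 at a negative fold change and lay at the threshold (median −0.08, camera adjusted p = 0.0527; adjusted p = 0.591 with an estimated correlation). They were called lower with no filter (camera adjusted p = 0.0338), a stricter filter (0.0488), a pseudocount of 5 (0.0496), scaled reads (0.0245) and protein-coding genes alone (0.0442). They were also called without DMSO library 2 (median −0.09, camera adjusted p = 0.0388) and without CBR-5884 library 2 (median −0.13, camera adjusted p = 0.0382), but not without DMSO library 4 (median −0.06, camera adjusted p = 0.551) or CBR-5884 library 4 (median −0.05, camera adjusted p = 0.212). Replication and mitosis genes had 23 of 28 at a negative fold change (median −0.05, camera adjusted p = 0.0527; 0.0262 with no filter and 0.0496 with a pseudocount of 5; median −0.03 without DMSO library 4). The adjusted p was 0.591 with an estimated correlation and 0.529 with fry. Mki67 was at 93.9 ± 7.32 and 95.2 ± 11.5 TPM (SD, n = 2).

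The p53 targets and apoptosis list had a median of −0.07 over 22 (camera adjusted p = 0.123), with Cdkn1a at 15.9 ± 2.56 and 13.3 ± 3.89 TPM (SD, n = 2). It was called lower without DMSO library 2 (median −0.10, camera adjusted p = 0.0331) and without CBR-5884 library 4 (median −0.08, camera adjusted p = 0.0469). Its median was 0.01 without CBR-5884 library 2 (camera adjusted p = 0.587) and −0.04 without DMSO library 4 (camera adjusted p = 0.917). With all libraries and an estimated correlation the adjusted p was 0.591 for this list and 0.921 for the immediate early genes. Antioxidant genes had a median of 0.05 over 18 (camera adjusted p = 0.221), glycolysis genes 0.01 over 18 (camera adjusted p = 0.211) and immediate early genes 0.06 over 19 (camera adjusted p = 0.704). The antioxidant median was −0.04 without DMSO library 4, and the glycolysis median 0.08 without DMSO library 2. The immediate early list was called higher without CBR-5884 library 2 (median 0.20, camera adjusted p = 0.0073). Its test turned downwards without CBR-5884 library 4 (median −0.12, camera adjusted p = 0.0547) and without DMSO library 4 (median −0.05, camera adjusted p = 0.736).

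**Figure D3:**
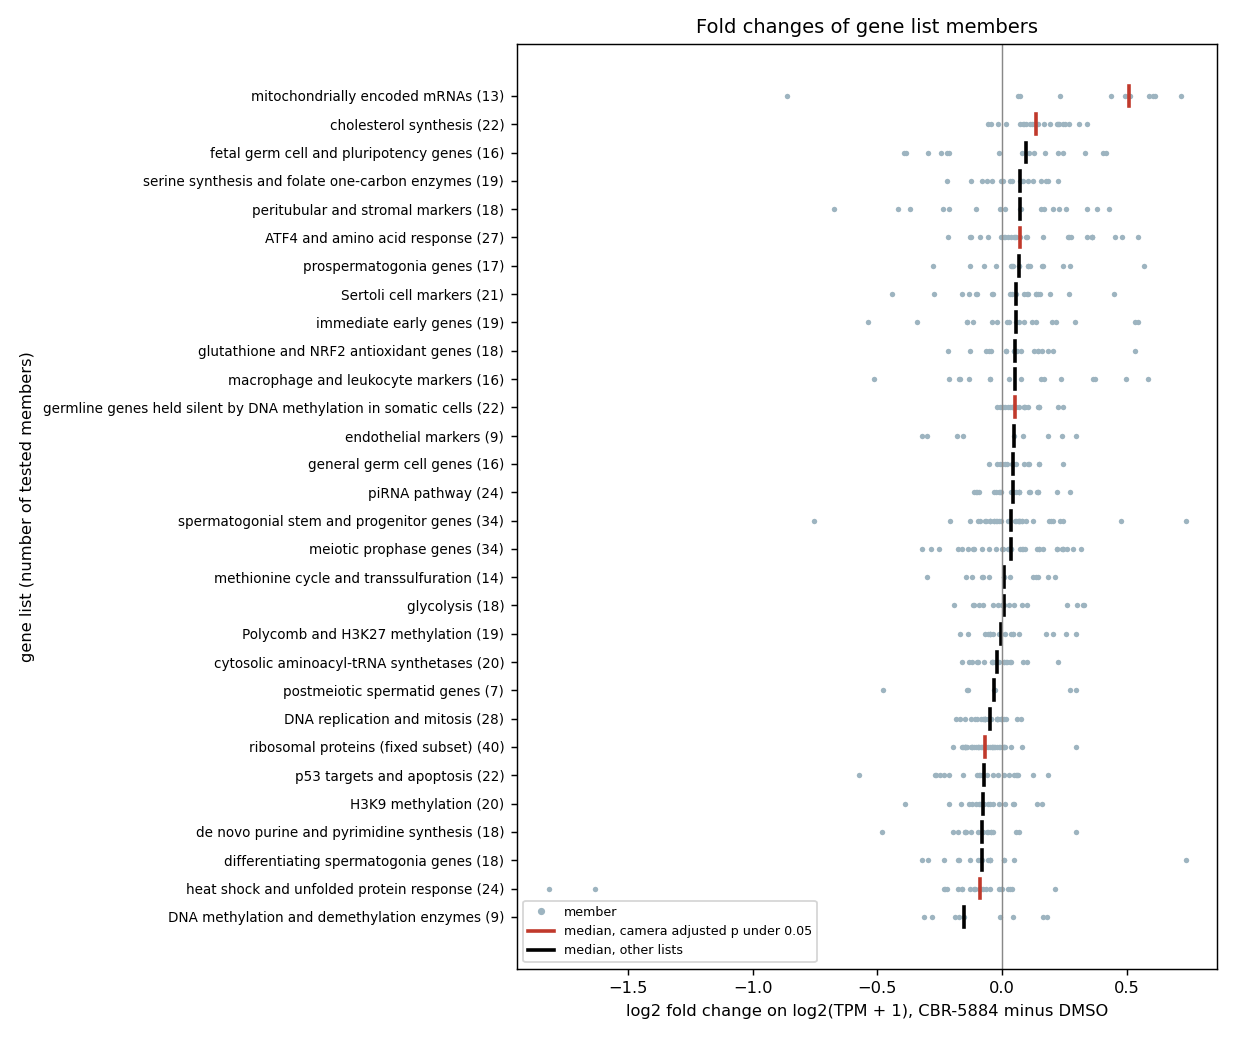
Fold changes (log2, CBR-5884 minus DMSO) of the tested members of each of the 30 tested gene lists, with a point per gene and a bar at the list's median, red where the camera adjusted p was under 0.05 and black elsewhere. The median of the mitochondrially encoded mRNAs is 0.51, while those of the other lists lie between −0.15 and 0.14.

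Markers of other testis cells were present at low to moderate levels and did not separate the conditions. Sertoli cell markers had a median of 0.06 over 21 tested genes (camera adjusted p = 0.704), with Sox9 at 7.49 ± 2.99 and 7.43 ± 0.84 TPM (SD, n = 2). Peritubular and stromal markers had a median of 0.07 over 18 (camera adjusted p = 0.523; −0.17 without DMSO library 4 and 0.15 without DMSO library 2), endothelial markers 0.05 over 9 with a test direction downwards (camera adjusted p = 0.783; −0.06 without either CBR-5884 library) and macrophage and leukocyte markers 0.05 over 16 (camera adjusted p = 0.487). Only 4 of 14 Leydig cell genes and 1 of 10 erythroid genes of the table reached a mean TPM of 1, so these lists were not tested. Sertoli markers differed between libraries within a condition. Amh, a hormone of Sertoli cells, had 38.5 TPM in DMSO library 2 and 16.6 TPM in DMSO library 4, and 29.6 and 26.5 TPM in the CBR-5884 libraries 2 and 4. The Sertoli list was called lower without DMSO library 4 (median −0.33) and higher without DMSO library 2 (median 0.42). The macrophage list was called lower without CBR-5884 library 4 (median −0.42) and higher without CBR-5884 library 2 (median 0.58).

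**Figure D4:**
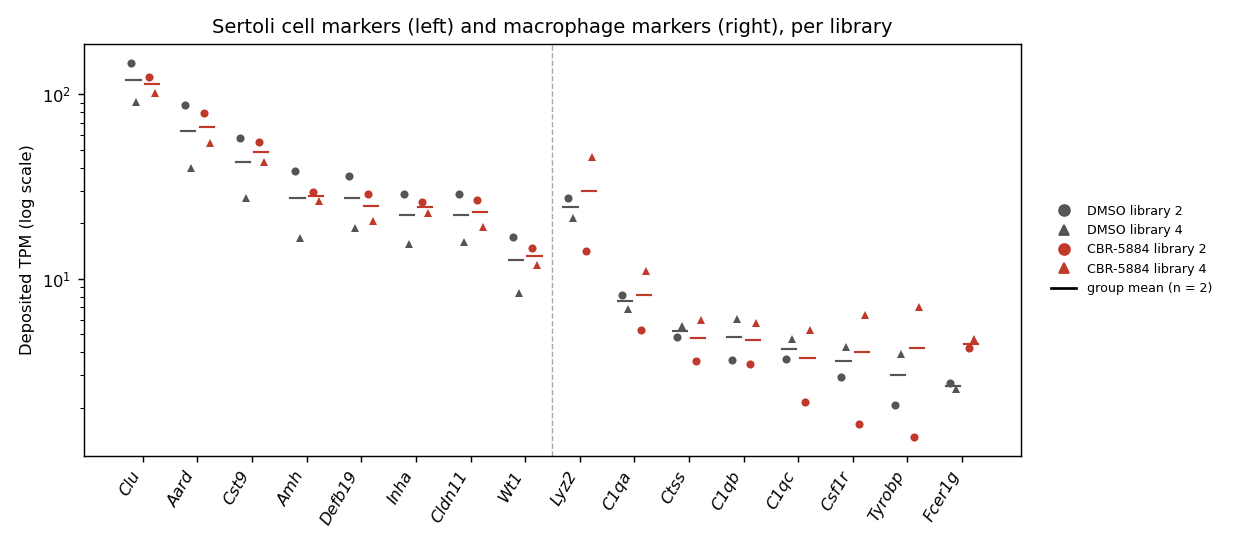
Deposited TPM (log scale) of the 8 most abundant tested Sertoli cell markers and the 8 most abundant tested macrophage and leukocyte markers in each of the 4 libraries, with grey points for DMSO, red points for CBR-5884, circles for library 2, triangles for library 4 and a line for each group's mean (n = 2). Amh lies at 38.5 and 16.6 TPM in the DMSO libraries, and Csf1r at 1.64 and 6.34 TPM in the CBR-5884 libraries.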

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

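The other measures, scalings, pseudocounts, robust variances and the restriction to protein-coding genes were chosen after the data were seen. Genes higher and lower with CBR-5884 stayed at 0 and 0 in all alternatives but 3. Protein-coding genes alone gave 1 higher (Gm11172, adjusted p = 0.0428) and 1 lower (Hspa1b, adjusted p = 0.0243), scaled reads gave 1 lower (Hspa1b, adjusted p = 0.0246) and robust variances gave 1 higher (adjusted p = 0.0391); the smallest limma adjusted p over all alternatives lay between 0.0243 and 0.882. The number of lists called, 6, was 0 with an estimated correlation and 0 with fry, and 6 to 9 under the other filters, measures, scalings, pseudocounts, robust variances and protein-coding genes alone. With a library left out it ranged from 3 (without DMSO library 4) to 13 (without DMSO library 2); a lone library is then assumed to vary like the others. Without a library, the direction of the list test turned in 9 lists. In 3 of them the list was past the threshold with all libraries or without that one: Sertoli markers (medians −0.33 to 0.42), macrophage markers (−0.42 to 0.58) and ribosomal proteins (−0.15 to 0.01). The other 6 were uncalled in both fits. Leaving out a library added a call in 10 lists and ended one in 4 of the 6 called. The mitochondrial list stayed called in each of these fits, with medians of 0.43 to 0.51. With the library number of the table as a replicate block 10 lists and 0 genes were called, the 6 lists and nucleotide synthesis (adjusted p = 0.029), replication and mitosis (0.0477), differentiating spermatogonia (0.029) and general germ cell genes (0.0466). That number is not shown to pair libraries: the labels give no shared origin, there are 2 pairs, and the deviations of same-numbered libraries correlated at 0.20 across genes. Of 503 values of 36 named genes under 14 alternatives 27 changed sign, in 18 genes. Of 480 list tests of 30 lists under 16 alternatives, 20 turned direction, in 9 lists. That count follows the direction of the test, not the sign of the median. The antioxidant median, for example, went from 0.054 to −0.044 without DMSO library 4 while the test direction held. Dnmt3l had no value under the stricter filter, which it did not pass. The causes were not tested. Not run, since the values are not counts: edgeR, DESeq2, voom, TMM and RLE factors, library size alone and length offsets. Precision was limited by 2 libraries per condition.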

Other observations

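The test of summed Hspa1a and Hspa1b, that of the nuclear copies of mitochondrial sequence, the contrast of library numbers, the requirement that a marker difference hold within both conditions, and the tests of added lists and library numbers with an estimated correlation were chosen after the data were seen. The libraries numbered 2 and 4 in the table differed from each other more than the conditions did. With no covariate, limma called 18 genes between the numbers, 0 between CBR-5884 and DMSO and 1 in the crossed split, with 1247, 546 and 449 genes at an unadjusted p under 0.05; 3 splits are too few for a share under 0.05. With the condition as a covariate 19 genes were called, 7 higher and 12 lower in the libraries numbered 4. Of these, 13 are not protein-coding, against 10.4% of the tested genes. Examples, chosen after their values were seen, are Sfi1, a centrosome protein, at 30.3 and 84.5 TPM in DMSO libraries 2 and 4 and at 25.1 and 71.8 TPM in CBR-5884 libraries 2 and 4, and the X-linked germ cell gene Luzp4, at 27.5 and 3.09 TPM and at 23.1 and 1.65 TPM.

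By list, camera called 6 lists between the library numbers, none of them with an estimated correlation (adjusted p = 0.807 for each). Of these, 3 were also called between the conditions: cholesterol synthesis (median log2 difference −0.10 for number 4 minus 2, camera adjusted p = 0.00328), heat shock and unfolded protein response (0.055, adjusted p = 0.029) and silenced germline genes (−0.10, adjusted p = 0.029). The other 3 were general germ cell genes (−0.09, adjusted p = 0.034), Sertoli markers (adjusted p = 1.41e-07) and macrophage markers (adjusted p = 8.25e-07).

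Markers of Sertoli cells and macrophages differed with the library number, by unequal amounts in both conditions. Sertoli cell markers were lower in the libraries numbered 4 (median log2 difference −0.59, interval −0.63 to −0.47, 21 genes) and higher in library 2 than in library 4 of both conditions for 16 of the 21; the median was −0.83 within DMSO and −0.18 within CBR-5884. Macrophage and leukocyte markers were higher in the libraries numbered 4 (median 0.60, interval 0.44 to 0.67, 16 genes; 12 of 16 in both conditions), with medians of 0.34 within DMSO and 0.78 within CBR-5884. Stromal and endothelial markers had medians of −0.095 and 0.02. Reads shared among near-identical copies as the whole account are argued against, since the deviations of same-numbered libraries still correlated at 0.186 over 13373 protein-coding genes. Other testis cells carried through the sort in different amounts stay open. The bound set beforehand, a median of 0.5 or more in size in any list, was met by macrophage (0.604) and Sertoli markers (−0.592). Meeting it restates the marker difference itself. By the requirement added after the data were seen, no list differed by 0.5 or more within both conditions. The most abundant of these markers were Clu, at 148, 90.3, 125 and 102 TPM, and Lyz2, at 27.4, 21.3, 14.2 and 45.5 TPM, in DMSO libraries 2 and 4 and CBR-5884 libraries 2 and 4. No gene of either list stands in another list. A lower share of germ cells by itself would raise both lists, and they moved in opposite directions. No biological explanation was tested.

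The mitochondrially encoded mRNAs lay higher with CBR-5884 as a list by camera, a call lost with an estimated correlation (adjusted p = 0.463) and with fry (adjusted p = 0.36); 0 members passed the threshold over all genes with limma, 10 had an unadjusted p under 0.05, and mt-Nd3 went the other way. If the difference holds, a rise of the respiratory chain as a whole is argued against, because 74 nuclear-encoded subunit genes had a median of −0.041. The interval over genes was −0.066 to −0.026, without the spread between libraries. Reads moved from nuclear copies of mitochondrial sequence are argued against too: the scaled reads summed over the 13 mRNAs and 12 nuclear copies rose by at least 0.346 on the log2 scale in each pairing of a CBR-5884 with a DMSO library. For carry-over of RNA without long poly(A) tails, 39 replication-dependent histone genes had a median of −0.448 (interval over genes −0.676 to −0.023). The upper bound lay under 0.3, which by the rule set beforehand counts against carry-over. However, 28 of the 39 had a mean under 5 TPM, and the other 11 had a median of −0.12 with an interval of −0.99 to 0.34. The cut at 5 TPM was not part of that rule. Carry-over is left open here because most of these genes were that low. An effect of CBR-5884 on mitochondrial transcripts may also account for it and was not tested further.

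Hspa1a and Hspa1b had lower values in both CBR-5884 libraries, short of the threshold over all genes (limma adjusted p = 0.253 and 0.141). Reads traded between the 2 near-identical genes are argued against, since the log2 ratio of their summed TPM was −1.382 or lower in every pairing. For a heat shock response that differed as a whole, from handling or treatment, a median of −0.3 or lower was set beforehand. The 20 other heat-inducible chaperones had a median of −0.078 (interval over genes −0.151 to −0.036), with 16 of the 20 below 0. A fall of the set size in these genes as a whole is argued against. A weaker or uneven response stays open, since the median cannot decide on it. The camera call of this list (adjusted p = 0.017) was lost with an estimated correlation (adjusted p = 0.599) and with fry (adjusted p = 0.257). Among the 20, Bag3 and Hspb1 fell furthest, with log2 fold changes of −0.461 (SE 0.206) and −0.319 (SE 0.231). Dnajb4 rose furthest (0.231, SE 0.186). Hsph1 had 134 and 163 TPM with DMSO and 121 and 130 TPM with CBR-5884. Of the 20, 6 also stand in the heat shock and unfolded protein response list. An effect of CBR-5884 or of handling on Hspa1a and Hspa1b alone may also account for the difference and was not tested.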
